A study of Panicum virgatum with 40 samples.

How the data were processed

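Messenger RNA was sequenced from the crown, the stem base from which shoots and roots arise, of switchgrass (Panicum virgatum) plants grown in a greenhouse in 3.6 L pots. Total RNA was extracted with TRIzol and libraries were made with a Kapa Biosystems preparation, per the labels' protocols, and sequenced as paired ends on an Illumina instrument, per the series' design text. The 40 libraries come from 5 genotypes: the octoploid individuals 1-78, 2-37 and 2-43, the tetraploid cultivar Liberty and the octoploid cultivar Trailblazer. Each genotype was sampled after 7 weeks of water stress (17 libraries), after 7 weeks of water stress and 1 week of renewed watering (13 libraries), after 7 weeks of watering (5 libraries) and after 8 weeks of watering (5 libraries). One line of the treatment protocol sets the name used for watered plants beside the stress treatment. The titles and the water status of the samples put those libraries with the watered plants, and they were used that way. The labels number the libraries by block, with 5 blocks in all. Nothing in the labels says whether libraries of a genotype came from separate plants, so p-values measure only the spread between these libraries.

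The authors deposited whole-number counts of reads per gene for 91838 gene IDs, with no normalization, 1 column per library. The submitters' processing notes name bcl2fastq, which turns sequencer output into reads, and DESeq2, both without a version or a role. The aligner, the read counter, the genome build, the annotation and the use of strand are not given in the sources used here. Genes of near-identical sequence, which are common in a polyploid genome with K and N subgenomes, could share or lose reads in that counting, so the level of a single gene ID is uncertain to that extent. Total counts per library ran from 4006128 to 7242351, and 13398 gene IDs had no count in any library. A single gene took 2.35% to 13.8% of the counts of a drought library. For 0 counts over a group, the upper limit was set at 3 counts over the summed TMM-scaled totals of that group. Ratios that rest on 1 to 3 counts are given with an exact 95% interval. Intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules.

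Genes with at least 1 count per 1e+06 counts of the library total (CPM) in at least 5 libraries were tested, which left 50219 genes holding at least 99.26% of the counts of each library. Counts were compared with edgeR 4.0.16 under R 4.3.3, with TMM normalization, a quasi-likelihood fit over all 40 libraries with additive terms for genotype and water treatment, and the quasi-likelihood F-test. P-values were adjusted by Benjamini and Hochberg's method over the genes tested, with 0.05 as the threshold. Whether genotypes differed in their response was tested by F-tests of interaction in separate fits, over the 22 libraries of week 7 and over the 30 drought and recovery libraries. Log2 fold changes of edgeR came from the fit, with its default prior count. Their standard errors were worked back as the absolute log2 change over the square root of the F statistic, and so are approximate. Log2 CPM values, used for principal components, correlations and medians per library, had a prior count of 2. CPM values of genes are counts per 1e+06 of the library total scaled by its TMM factor, so they differ somewhat from shares of the counts, and are means over libraries with the SD; CPM values summed over marker genes use the unscaled totals. Values per library, such as the share of the most abundant gene, were compared by permutation of the water labels within genotypes, two-sided, exact where all rearrangements could be listed and otherwise with 100000 draws, adjusted over the 32 tests of that family. Enrichment on subgenomes and chromosomes, as the letters of the gene IDs give them, was tested by two-sided Fisher's exact test against all genes tested.

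No gene could be named. The table of gene names for this organism (assembly P.virgatum_v5) matched 0 of the gene IDs, the deposited table does not pair IDs with names, and IDs are used as deposited. The 25 gene lists fixed for drought responses could therefore not be filled. The rule for naming genes, fixed for that case, took the 2 largest rises and the 2 largest falls per comparison among genes past the threshold with a mean CPM of at least 5 over the libraries compared. The most abundant gene, Pavir.4NG154200, and the genes of the interactions were added after their values were seen.

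Groups shared block numbers, and the labels present the number as a block. The main fits and the permutation tests left the block out, so their p-values do not pair libraries of a block. A fit with the replicate block as a term was set beside the main fit. The mean correlation of the libraries' deviations from the fitted values was -0.04 over 107 pairs of the same block and week and -0.04 over 238 pairs of other blocks in the same week. All watered libraries of week 7 were in block 1 and all watered libraries of week 8 in block 5. Block and watering are thus only partly separated. The water term takes up a block effect shared by the watered libraries of a week, so the correlations above cannot exclude one. Week of harvest also differed between drought and recovery.

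The designs, the groups and most alternatives were set before the data were examined. The alternatives were DESeq2 size factors, DESeq2 1.42.0 with Wald and likelihood ratio tests, no filter, a stricter filter of 20 libraries, the replicate block, blocks 1 and 5 alone, the 2 treatments compared alone, all genotypes but 2-37, and each library left out in turn. Others were chosen after seeing the data: leaving out 2 outlying drought libraries, 2 recovery libraries with markers of both 1-78 and 2-43, or the most abundant gene, using 1 block alone, leaving 1 genotype out of the interaction tests, leaving out the highest library of the higher group for lower limits and pooled ratios, and other count minimums for genes without counts in a genotype. The procedure was tested on simulated counts with the libraries' own totals and a single mean per gene over all libraries, in which 200 of the genes were changed. The simulated spread followed the trend of dispersion over expression level alone. It held no genotype differences, no spread particular to a gene and no outlying libraries, so the rates may be too high for these data. For drought against watering it recovered 8.96% of the 67 genes changed 2-fold, 70.1% of those changed 4-fold and 89.4% of the 66 changed 8-fold. For recovery against watering it recovered 8.96%, 61.2% and 93.9%, and for recovery against drought 31.3%, 82.1% and 98.5%. For the watered groups it recovered 1.49%, 44.8% and 74.2%. For the change of the difference between drought and recovery it recovered 4.48%, 25.4% and 71.2%, for the individuals against Liberty 16.4%, 82.1% and 95.5%, for Trailblazer against Liberty 5.97%, 53.7% and 89.4%, and among the individuals 7.46%, 62.7% and 84.8%. For both interactions it recovered 0% at each size when the 2 Liberty libraries of 1 treatment were changed.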

Results

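Crown expression was measured in 40 libraries of 5 switchgrass genotypes under 4 water treatments. Drought plants (7 weeks of water stress) gave 5 libraries each of 1-78 and 2-43, 3 of 2-37 and 2 each of Liberty and Trailblazer. Recovery plants, watered again for 1 week, gave 4 libraries each of 1-78 and 2-43, 1 of 2-37 and 2 of each cultivar. Each genotype had 1 library watered for 7 weeks and 1 watered for 8 weeks. Total counts were 5297000 ± 553000 (SD, n = 17) in drought libraries, 5202000 ± 962000 (n = 13) in recovery libraries, 5305000 ± 483000 (n = 5) at 7 weeks of watering and 5805000 ± 1090000 (n = 5) at 8 weeks. Between 49680 and 56479 gene IDs had counts in a library. The first principal component of the tested genes held 17.1% of the variance and the second 9.37%.

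**Figure D1:**
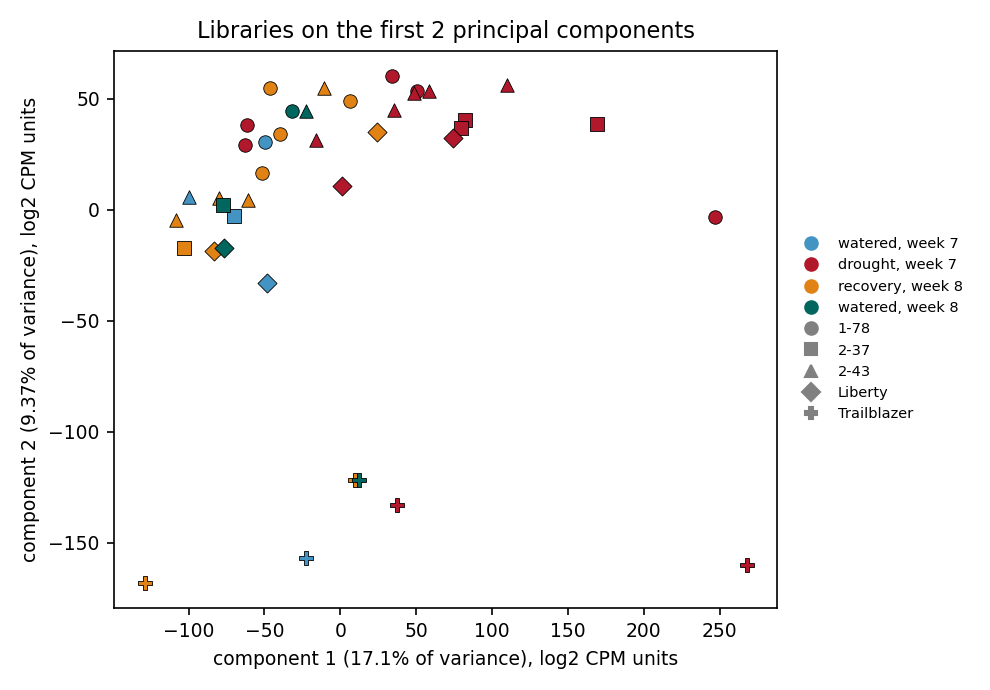
The 40 libraries on the first 2 principal components of log2 CPM, which hold 17.1% and 9.37% of the variance; color gives the water treatment and shape the genotype, 1 point per library. The 6 Trailblazer libraries lie low on the second component, and the drought libraries of 1-78 in block 11 and of Trailblazer in block 5 lie at 247 and 268 on the first.

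The recovery libraries of 1-78 and of 2-43 in block 1 were closer to each other than any other 2 of the 40 libraries were, with a chi-square of 8.85 per gene, the lowest of 780 pairs, and 11.9 in the next. The 1-78 library had counts for 36 of 63 markers of 2-43 (genes with counts in most other libraries of 2-43 and in no other library of 1-78), and the 2-43 library for 16 of 23 markers of 1-78, chosen likewise. Of the markers of their own individual they had nearly the same numbers, 16 of 23 in the 1-78 library and 37 of 63 in the 2-43 library. Each comparison they enter was also run without them. With treatment means removed and each library kept out of its own genotype's mean, 35 of the 40 libraries correlated best with their own genotype. Among the others were these 2, the 2-43 library at 0.186 with 1-78 and 0.037 with 2-43, and the 1-78 library at 0.085 with 2-43 and 0.077 with 1-78. The rest were the 1-78 drought library of block 11 (0.146 with Trailblazer, -0.125 with 1-78) and the Liberty recovery libraries of block 1 (0.016 with 2-37, -0.075 with Liberty) and block 5 (0.022 with 2-37, 0.009 with Liberty).

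**Figure D2:**
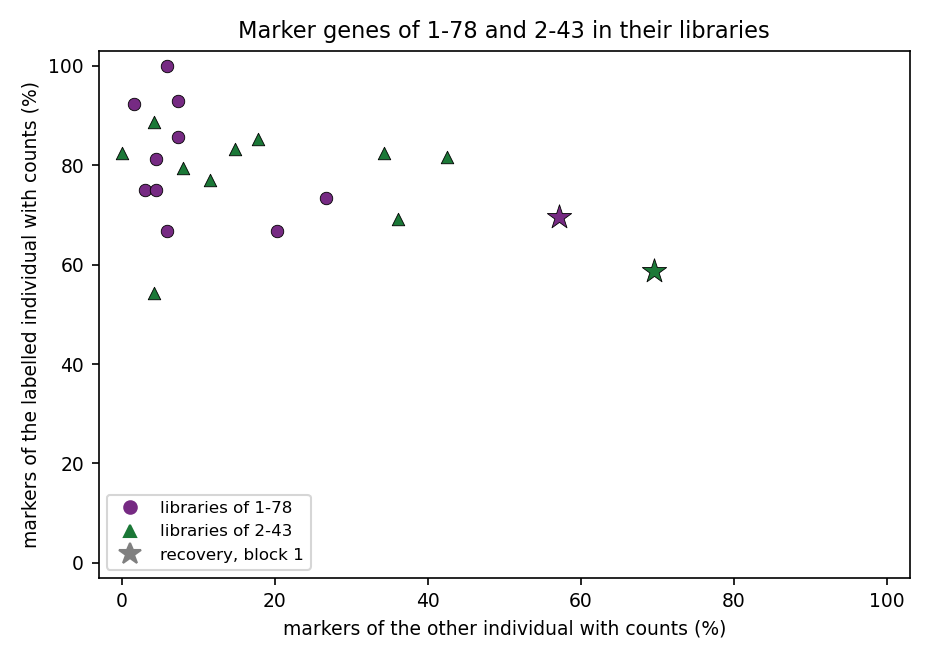
Percent of the marker genes of the library's own individual with counts (vertical) against percent of those of the other individual with counts (horizontal), 1 point per library of 1-78 and 2-43; stars mark the recovery libraries of block 1. The stars lie at 57.1% and 69.6% of the other individual's markers, and the other libraries at up to 26.7% in 1-78 and 42.5% in 2-43.

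How crowns under 7 weeks of water stress differed from crowns watered for 7 weeks was the first comparison. Pavir.6NG184400 reached 112 ± 333 CPM (SD, n = 17) under drought, with counts in 13 of the 17 libraries and a median of 1.35 CPM. It had 0 counts in the 5 watered libraries, which makes it at least 959-fold higher under drought against the limit of 3 counts over the watered group (edgeR adjusted p = 0.015). Pavir.8NG035100 averaged 28.5 ± 71.4 CPM in drought libraries with a median of 3.14, had counts in 16 of the 17 and 0 in watered ones, and was at least 245-fold higher (adjusted p = 0.004). Both genes were highest in the Trailblazer drought library of block 5, at 1290 and 294 CPM, and without it the limits were 328-fold and 102-fold. Without that library Pavir.6NG184400 averaged 38.2 ± 143 CPM (n = 16), with 573 CPM in a 1-78 drought library. Pavir.3NG016500 fell from 23.1 ± 41.5 CPM (n = 5) to 0.0662 ± 0.151 CPM, a log2 change of -7.49 ± 1.05 (SE; adjusted p = 3e-05), with 96.4 CPM in the watered Trailblazer library and at most 15.2 in the other watered libraries. Pavir.7NG041200 fell from 31.2 ± 28.5 to 0.371 ± 1.19 CPM (log2 change -7.29 ± 1.21, adjusted p = 0.00022). Without the drought libraries of 1-78 in block 11 and of Trailblazer in block 5, the log2 change of Pavir.6NG184400 was 6.43 (adjusted p = 0.0062). Its adjusted p was 0.059 without the watered 1-78 library, 0.086 without the watered Trailblazer library, 0.073 in blocks 1 and 5 alone and 0.11 in a fit of the 2 treatments alone, in which that of Pavir.8NG035100 was 0.065. Within block 1 alone the adjusted p of the 4 genes ran from 0.15 to 0.25.

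In all, 3344 of 50219 genes passed the threshold, 1551 higher under drought with a median log2 change of 1.07 and 1793 lower with a median of -1.72. Among genes on the K and N subgenomes, 694 of the 1498 higher genes (46.3%) were on K, against 51.5% of the genes tested (Fisher's exact test, adjusted p = 0.000622 over 12 tests). Of the 1710 lower genes, 935 (54.7%) were on K (adjusted p = 0.0434); the unadjusted p was 0.0782 in blocks 1 and 5 alone and 0.0581 in a fit of the 2 treatments alone. The lower genes were few on the chromosomes 8K and 8N, which each held 1.17% of them against 3.05% and 2.82% of the genes tested (adjusted p = 1.92e-05 and 0.000118 over 216 tests). Chromosome 3N held 1.62% of the lower genes (adjusted p = 0.000772) and 4.96% of the higher genes (adjusted p = 0.00311) against 3.2% of those tested. Chromosome 1K held 3.42% of the higher genes against 5.93% of those tested (adjusted p = 0.000247). The higher genes were also frequent on 8N, 9N and 1N (adjusted p = 0.0197, 0.0212 and 0.0248) and infrequent on 5N and 2K (0.0374 and 0.0478). The lower genes were frequent on 3K (0.0478). Unplaced IDs made up 3.42% of the higher genes against 5.25% of those tested (adjusted p = 0.00188 over 12 tests). Fisher's test takes genes as independent, and genes with neighbouring IDs were called together 1.53 times as often as in random orders. When the genes were chosen without the libraries of a genotype, between 72.3% and 94% of them lay on the called side in each of its drought libraries, relative to its own watered library. The median log2 change of the lower genes averaged -1.49 ± 0.58 (SD, n = 5) in 1-78, -1.51 ± 0.38 (n = 3) in 2-37, -0.91 ± 0.49 (n = 5) in 2-43, -1.59 ± 0.57 (n = 2) in Liberty and -2.03 ± 0.42 (n = 2) in Trailblazer. With the replicate block as a term 1053 genes passed, 322 of them higher, and within block 1 alone 1 gene passed. The count moved with single watered libraries: it was 1356 without that of Liberty, 1615 without that of Trailblazer, 1698 without that of 2-37 and 2028 without that of 1-78.

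**Figure D3:**
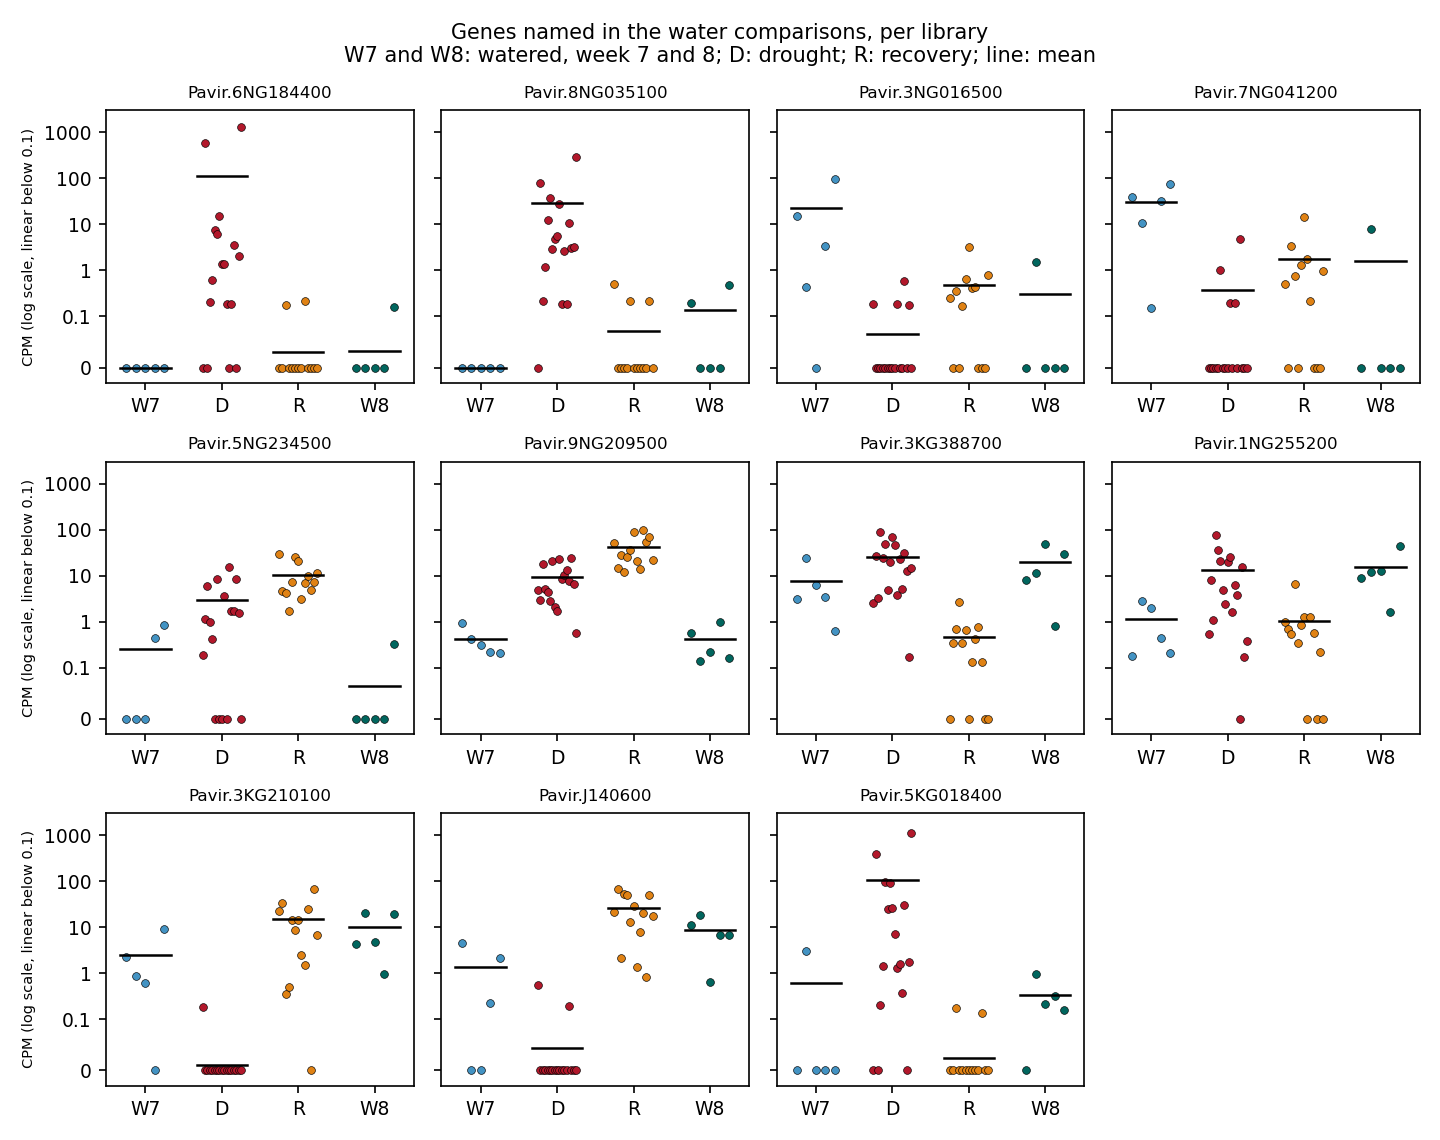
CPM per library, on a log axis that is linear below 0.1, of the genes named for drought, recovery and rewatering, by water treatment, with 1 point per library and a line at the mean. Pavir.6NG184400 is at 0 in the 5 libraries watered for 7 weeks, and its mean of 112 CPM under drought lies far above its median of 1.35.

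Whether crowns were back at the level of watered plants after 1 week of renewed watering was asked against the plants watered for 8 weeks. Pavir.5NG234500 stood at 10.5 ± 8.9 CPM (SD, n = 13) in recovery libraries and had 2 counts in the 5 watered libraries, a ratio of pooled counts of 147 (95% counting interval 40.4 to 1210; adjusted p = 0.026). Pavir.9NG209500 stood at 41.1 ± 28.8 CPM against 0.412 ± 0.356 CPM (n = 5), a log2 difference of 6.63 ± 0.85 (SE; adjusted p = 0.00017). Pavir.3KG388700 was lower in recovery, at 0.477 ± 0.723 against 20.1 ± 19.8 CPM (log2 -5.71 ± 0.92, adjusted p = 0.0016), as was Pavir.1NG255200, at 1.03 ± 1.74 against 15.7 ± 16.2 CPM (log2 -4.88 ± 1.09, adjusted p = 0.025). In all, 274 genes passed, 90 higher and 184 lower in recovery. The 1551 genes higher under drought had a median log2 difference of 0.02 in recovery, with 52.3% of them on the higher side, and the 1793 genes lower under drought had a median of -0.39, with 73.6% on the lower side. Of the genes called in recovery, 23 of the 90 higher ones were also higher under drought (2.78 for independent lists; Fisher's exact test, p = 3.41e-15), and 27 of the 184 lower ones were also lower under drought (6.57; p = 5.43e-10). The drought and recovery comparisons share no library but come from 1 fit with shared genotype terms, and Fisher's test takes genes as independent. The numbers in common moved with single watered libraries: without that of week 8 of 2-43, Trailblazer, 2-37 or Liberty they were 5, 9, 14 and 15 for higher genes and 3, 6, 11 and 14 for lower genes. Without that of week 7 of Liberty or Trailblazer they were 9 and 12 for higher genes and 16 and 17 for lower genes. Without the week 7 library of 2-37 there were 10 higher genes in common, and without that of 2-43 there were 41 lower ones. Without 1 recovery library there were 14 and 15 lower genes in common (Liberty, blocks 1 and 5), 14 (2-43, block 11) or 42 (1-78, block 9). With the replicate block 7 higher genes were in common, and without the recovery libraries of 1-78 and 2-43 in block 1 there were 12 lower ones. Blocks 1 and 5 alone gave 11 higher and 17 lower genes in common, and the 2 treatments alone 12 higher ones. The fit without the 2 outlying drought libraries (1-78 in block 11, Trailblazer in block 5) gave 37 and 51, and DESeq2 gave 115 and 99.

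The recovery count moved with single libraries: 25 genes passed without the watered 2-43 library, 58 without the watered Trailblazer library and 166 without the 2-43 recovery library of block 11. It was 139 without the genotype 2-37, and 182 without the recovery libraries of 1-78 and 2-43 in block 1, each of which held counts for markers of both individuals. Within block 5 alone it was 0 (edgeR, 4871 genes at an unadjusted p under 0.05). Over all blocks DESeq2 called 1021. The adjusted p of Pavir.5NG234500 ran from 0.06 to 0.15 when the watered library of any 1 genotype was left out, and that of Pavir.1NG255200 was 0.19 without the watered Trailblazer library, 0.1 without that of 2-43, 0.052 without the Trailblazer recovery library of block 1 and 0.051 without both block 1 recovery libraries of 1-78 and 2-43.

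Whether the difference from watered plants itself changed between drought and recovery was tested next. Pavir.7KG065200 was at 1.44 ± 3.81 CPM (n = 17) under drought against 110 ± 94.2 CPM (n = 5) in the matching watered plants, and at 7.66 ± 18.3 CPM (n = 13) in recovery against 6.16 ± 13 CPM (n = 5). The fit with genotype terms, which does not work from these means, put the rise of its log2 difference at 9.06 ± 2.19 (SE; adjusted p = 0.036). For Pavir.6KG113900 the means were 7.93 ± 17 against 35.4 ± 42.6 CPM under drought and 75.9 ± 109 against 1.38 ± 0.939 CPM in recovery (8.35 ± 1.91, adjusted p = 0.027). Pavir.1NG096300 went the other way, with 30.2 ± 44.8 against 0.889 ± 0.868 CPM under drought and 0.277 ± 0.332 against 8.21 ± 7.36 CPM in recovery (-10.34 ± 1.6, adjusted p = 0.0027). Pavir.7NG002700 had 102 ± 229 against 10.8 ± 22.4 CPM under drought and 0.0832 ± 0.0983 against 9.74 ± 15.9 CPM in recovery (-10.16 ± 2.02, adjusted p = 0.011). In all, 490 genes passed, 180 with a rise and 310 with a fall of the difference. With the replicate block 13 genes passed. The change was then 7.12 for Pavir.7KG065200 (edgeR adjusted p = 0.21) and 8.16 for Pavir.6KG113900 (0.11). It was -8.85 for Pavir.7NG002700 (0.088) and -11.6 for Pavir.1NG096300 (0.0034). The count was 774 without the 1-78 drought library of block 1, from 160 to 311 without the week 7 watered library of any 1 genotype, and 113, 122, 197 and 299 without the week 8 watered library of 2-43, Trailblazer, 1-78 and Liberty. It was 320 without the 2-37 drought library of block 1, 300 without the 2-43 drought library of block 11, 326 without the 1-78 recovery library of block 7 and 323 without the 2-37 recovery library. Pavir.7KG065200 missed the threshold without any 1 of 10 libraries and Pavir.6KG113900 without any 1 of 7, with adjusted p of 0.11 and 0.088 without the week 8 Trailblazer library, and Pavir.7NG002700 was at 0.069 without that of 2-43.

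Which genes changed on renewed watering was read from recovery against drought, 2 groups harvested 1 week apart. Pavir.3KG210100 rose to 15.2 ± 19.2 CPM (SD, n = 13) from 1 count over the 17 drought libraries, a ratio of pooled counts of 1230 (95% counting interval 221 to 48800; adjusted p = 2e-08), and had counts in 12 of the 13 recovery libraries. Pavir.J140600 rose from 0.044 ± 0.14 to 25.7 ± 22.6 CPM (log2 change 8.68 ± 0.71, adjusted p = 1.1e-09). Pavir.6NG184400 had 2 counts over the recovery libraries, with a ratio of drought to recovery of 3870 (1070 to 32000; adjusted p = 7.8e-05), and Pavir.5KG018400 likewise had 2 counts, with a ratio of 3690 (1020 to 30400; adjusted p = 1.8e-05). In all, 8763 genes passed, 4431 higher and 4332 lower in recovery, with median log2 changes of 1.18 and -0.827. With 2 drought libraries left out, those of 1-78 in block 11 and Trailblazer in block 5, the log2 changes of Pavir.6NG184400 and Pavir.5KG018400 were -4.47 and -7.42 (adjusted p = 0.00055 and 6.1e-06). Without the Trailblazer library alone, which had 1290 and 1100 CPM of them, the ratios of pooled counts were 1170 (324 to 9680) and 1390 (386 to 11500). Blocks 1 and 5 alone gave 2279 genes.

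Between plants watered for 8 and for 7 weeks, edgeR called 0 genes, with 2945 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.131, and DESeq2 called 40. These 2 sets of 5 libraries came from different blocks and weeks. Leaving out 1 library gave 3 genes (the 2-43 library of week 7) or 1 gene (the 2-37 library of week 7, the Liberty drought library of block 1, or the 2-43 recovery library of block 11).

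The most abundant gene, Pavir.4NG154200, which was chosen after its values were seen, took 6.69% ± 4.27 (SD, n = 17) of the counts under drought, 0.637% ± 0.501 (n = 13) in recovery, 4.22% ± 3.69 (n = 5) at 7 weeks of watering and 2.31% ± 2.75 (n = 5) at 8 weeks. It was lower in recovery than under drought (log2 -3.62 ± 0.52, edgeR adjusted p = 7.4e-06; share of counts, permutation test, adjusted p = 0.00064). It did not pass between drought and watering (log2 0.94 ± 0.67, adjusted p = 0.44) or between recovery and watering (-1.57 ± 0.63, adjusted p = 0.32). Within block 1 its share was 6.64% ± 4.19 (n = 5) under drought and 0.45% ± 0.287 (n = 5) in recovery. Within block 5 it was 4.76% ± 3.73 (n = 5) and 0.982% ± 0.688 (n = 4). The K subgenome held 49.9% ± 2.41 of the counts on K and N under drought and 53.93% ± 0.835 in recovery (permutation test, adjusted p = 0.00032, from the smallest p that 100000 draws can give, 1e-05). Without Pavir.4NG154200, which is on an N chromosome, the shares were 53.59% ± 0.746 and 54.29% ± 0.695 (adjusted p = 0.131).

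**Figure D4:**
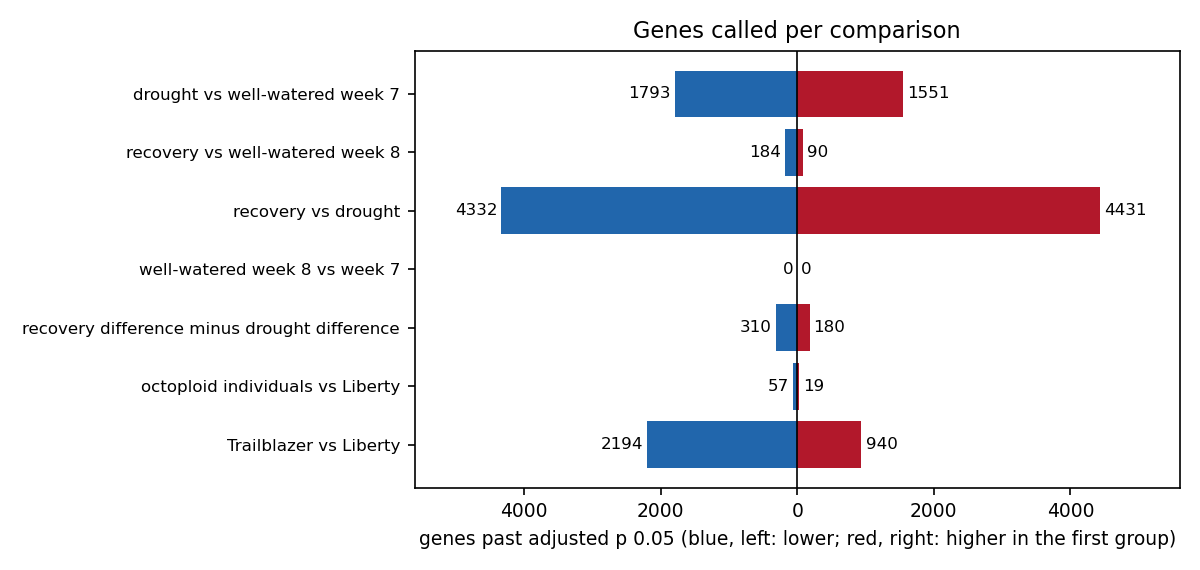
Genes past an adjusted p of 0.05 in each comparison, with bars to the right for genes higher in the first group named (or with a rise of the difference) and to the left for lower genes. Recovery against drought has 4431 higher and 4332 lower genes, and the 2 watered groups have 0.

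The 3 octoploid individuals were compared with the tetraploid cultivar Liberty. Pavir.7NG076500 was higher in the individuals, at 7.52 ± 5.16 CPM (SD, n = 28) against 0.142 ± 0.18 CPM (n = 6), a log2 difference of 5.4 ± 1.1 (SE; adjusted p = 0.022). Pavir.1NG051000 averaged 9.95 ± 5.03 CPM in the individuals, and had 5.07 CPM in 1 Liberty library, the drought library of block 1, and 0 in the others (log2 3.69 ± 0.74, adjusted p = 0.021). Pavir.2KG074200 was lower in the individuals, at 1.27 ± 1.25 CPM against 79.2 ± 191 CPM (log2 -5.63 ± 1.14, adjusted p = 0.022). Its Liberty mean came from 468 CPM in the recovery library of block 1, with at most 2.89 CPM in the other Liberty libraries, and that library correlated less with the mean of Liberty (-0.075) than with that of 2-37 (0.016). Pavir.1NG173100 stood at 6.14 ± 12 against 29.4 ± 34.1 CPM (log2 -3.23 ± 0.71, adjusted p = 0.043). In all, 76 genes passed, 19 higher and 57 lower in the individuals. With the replicate block 4 genes passed. The log2 differences of the 4 genes named, in the order above, were then 5.33, 4, -4.73 and -3.38, with edgeR adjusted p from 0.053 to 0.12. Without the Liberty drought library of block 1, 42 genes passed, and 45 passed without the Liberty recovery library of block 1. Without that recovery library the adjusted p was 1 for Pavir.2KG074200 (log2 -0.22), 0.34 for Pavir.1NG173100, 0.072 for Pavir.7NG076500 and 0.069 for Pavir.1NG051000, and without the week 8 Liberty library it was 0.17, 0.07 and 0.06 for the last 3. Pavir.1NG173100 missed the threshold under 28 of 49 alternatives, and Pavir.7NG076500 and Pavir.1NG051000 each under 5, all of them the block fit, blocks 1 and 5 alone or the removal of a Liberty library. With 1 tetraploid genotype, ploidy and genotype cannot be told apart.

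The octoploid cultivar Trailblazer differed from Liberty in 3134 genes, 940 higher and 2194 lower. Pavir.1KG477500 reached 111 ± 106 CPM (SD, n = 6) in Trailblazer, with counts in 5 of the 6 libraries, and had 0 counts in the 6 Liberty libraries, so it was at least 1230-fold higher in Trailblazer (adjusted p = 4.6e-05). Pavir.6NG045500 stood at 26.1 ± 19.9 CPM in Trailblazer and had 0 counts in Liberty, at least 290-fold higher (adjusted p = 0.0069). Pavir.5NG286300 had 0 counts in Trailblazer and 113 ± 132 CPM in Liberty, at least 1190-fold lower in Trailblazer (adjusted p = 3.1e-06), and Pavir.8KG379300 had 0 counts against 42.3 ± 55.2 CPM, at least 447-fold lower (adjusted p = 0.0062). Without the Liberty drought library of block 1 (353 CPM) the limit for Pavir.5NG286300 was 688-fold, and without the Liberty library watered for 7 weeks (132 CPM) that for Pavir.8KG379300 was 258-fold. Lower genes were frequent on chromosome 3N, with 5.38% of them against 3.2% of the genes tested (Fisher's exact test, adjusted p = 1.16e-05 over 216 tests), and on 8K, with 4.97% against 3.05% (adjusted p = 4.69e-05). They were infrequent on 9N, with 6.15% against 9.11% (adjusted p = 2.04e-05). The other chromosomes past the threshold were 8N, 7K, 6N and 4N with more of the lower genes and 5N, 9K, 2N and 1K with fewer (adjusted p from 0.000491 to 0.0478). Chromosome 3N also held more of the higher genes (5.32%, adjusted p = 0.00784). Unplaced IDs were frequent among the higher (8.09%) and the lower genes (7.34%) against 5.25% of those tested (Fisher's exact test, adjusted p = 0.000832 and 0.000184 over 12 tests). Fisher's test takes genes as independent, and genes with neighbouring IDs were called together 2.04 times as often as in random orders. These p-values can therefore be too small. Trailblazer differed from 1-78 in 5606 genes, from 2-43 in 5655 (3640 in blocks 1 and 5 alone) and from 2-37 in 3688. DESeq2 left Pavir.1KG477500 above the threshold (adjusted p = 0.16).

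Among the octoploid individuals, 1013 genes differed in an F-test over the 3. Without the recovery libraries of 1-78 and 2-43 in block 1 the test called 1232 genes, and in blocks 1 and 5 alone 124. It called 673 without the 2-37 drought library of block 5 and 665 without the 2-37 library watered for 8 weeks. With a CPM of at least 1 asked of 20 libraries it called 422.

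Whether genotypes differed in their drought response was tested over the 22 libraries of week 7, in which each genotype had 1 watered library, so that a watered level is that of a single library. Of 50219 genes 3 passed, with 1846 at an unadjusted p under 0.05, and all 3 are named here after their values were seen. Pavir.5NG341000 (adjusted p = 0.0093) had 0 CPM in both Trailblazer drought libraries, 47.2 CPM in its library watered for 7 weeks and from 63 to 176 CPM in the drought libraries of the other genotypes. It was also at 0 in the Trailblazer library watered for 8 weeks and in both Trailblazer recovery libraries. Pavir.5NG366400 (adjusted p = 0.013) was likewise at 0 in both Trailblazer drought libraries and at 8.8 CPM in its library watered for 7 weeks, while in Liberty it was at 0 watered for 7 weeks and at 12.7 and 18.2 CPM under drought. Outside week 7, it was at 9.67 CPM in the Trailblazer library watered for 8 weeks and at 0 in both Trailblazer recovery libraries, and in Liberty at 19.3 CPM watered for 8 weeks and at 34 and 0 CPM in recovery. Pavir.7KG102300 (adjusted p = 0.013) was at 0 in the libraries of Liberty and Trailblazer watered for 7 weeks, and averaged 15.5 and 5.51 CPM in their drought libraries. Watered for 8 weeks it was at 5.94 CPM in Liberty and at 0 in Trailblazer, and a Trailblazer recovery library, that of block 5, was at 0 too. For the change on renewed watering 3 genes passed too (3371 at an unadjusted p under 0.05). Pavir.7KG096500 (adjusted p = 0.023) rose in Liberty from 0 in both drought libraries to 19.7 CPM. Pavir.7KG433800 (adjusted p = 0.023) was at 10.4 CPM in Liberty under drought and at 0 in both recovery libraries. Pavir.J603500 (adjusted p = 0.023) was at 0 in both Trailblazer drought libraries and at 21.5 CPM in recovery. Each of these calls was lost in at least 1 fit with fewer libraries. Without the Trailblazer drought library of block 1 or of block 5 the adjusted p of Pavir.5NG341000 and of Pavir.5NG366400 was 0.078 or 0.062, and that of Pavir.J603500 0.095 or 0.3. Without the Liberty drought library of block 1 or of block 5 it was 0.22 or 0.12 for Pavir.7KG096500. Without the Liberty recovery library of block 1 or of block 5 it was 0.079 or 0.26 for Pavir.7KG433800. It was 0.053 for the 3 rewatering genes without the Trailblazer recovery library of block 5. Without the drought libraries of 1-78 in block 11 and Trailblazer in block 5, which leaves 1 Trailblazer drought library, 2 and 3 genes passed, with 1 and 0 of those named among them. A watered library of week 7 is the only one of its genotype, so the test was run without each genotype in turn, chosen after the data were seen. For drought 1 gene passed without Liberty and 0 passed without 1-78, 2-43 or Trailblazer (edgeR; 2134, 1446 and 2041 at an unadjusted p under 0.05), and the adjusted p of Pavir.7KG102300 was 0.54 without Liberty and 0.09 without Trailblazer. For rewatering 7 genes passed without 1-78, 6 without Trailblazer and 0 without Liberty (edgeR; 3783 at an unadjusted p under 0.05). In simulated data both tests recovered 0% of the genes changed in the 2 Liberty libraries of 1 treatment. DESeq2 called 169 and 197 genes, and with the replicate block edgeR called 0 (1829 at an unadjusted p under 0.05) and 1. The drought count was 1 without the Trailblazer drought library of block 1 and 5 without the 1-78 drought library of block 11. The rewatering count was 0 without the Trailblazer recovery library of block 5 (edgeR), 5 without that of block 1 or without the 2-37 drought library of block 1, 6 without the 1-78 drought library of block 7, 7 without the Trailblazer drought library of block 1, 9 and 15 without the Liberty drought library of block 1 and of block 5, and 11 without the Liberty recovery library of block 1.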

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

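The tests of the 2 recovery libraries that were closest to each other, the likeness of an outlying library to the genotype means and markers, and the splits without 2 outlying drought libraries, were chosen only after the results were seen.

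Of 66 sets of libraries and measures tested for a single outlying library, 13 had one; chance gives about 1 in 20 for independent values. Several of the 13 share a signal in 1 library, and named genes were picked for large differences, so no excess over chance is read from that number. The Trailblazer library watered for 8 weeks stood apart in 6 measures. Its most abundant gene took 7.23% of the counts (0.989% to 1.3% in the 4 other libraries of that treatment), its 50 most abundant genes 17.1% (9.24% to 11%), and the K subgenome 50% of the placed counts (53.1% to 54.1%). In the same library Pavir.4NG154200 was at 73184 CPM (9144 to 12925), Pavir.1NG255200 at 43.7 CPM (1.61 to 12.5) and Pavir.5NG234500 at 0.322 CPM (0 in the others). The 2-43 library watered for 8 weeks had counts for 51553 genes, against 55105 to 55744 in the others. In the Trailblazer library watered for 7 weeks Pavir.3NG016500 was at 96.4 CPM (0 to 15.2). In Liberty, Pavir.1NG051000 was at 5.07 CPM in the drought library of block 1 (0 in the others) and Pavir.2KG074200 at 468 CPM in the recovery library of block 1 (0 to 2.89). Among the drought libraries of 1-78, that of block 11 had 5.63% of its counts on unplaced gene IDs (2.72% to 2.91%), and that of block 5 had a K share of 52.9% without the most abundant gene (54% to 54.2%). The drought library of 2-43 in block 11 had a drought response (the median log2 difference of higher genes minus that of lower genes) of 2.81, against 0.97 to 1.48.

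In the test of whether the difference from watered plants changed between drought and recovery, 490 genes passed. With the replicate block as a term 13 passed, and 5 in blocks 1 and 5 alone. In the test of the drought response between genotypes 3 genes passed, Pavir.5NG341000 (adjusted p = 0.0093), Pavir.5NG366400 (0.013) and Pavir.7KG102300 (0.013). In that of the change on renewed watering 3 genes passed, Pavir.7KG096500 (0.023), Pavir.7KG433800 (0.023) and Pavir.J603500 (0.023). Without the drought libraries of 1-78 in block 11 and Trailblazer in block 5, 2 and 3 genes passed, of which 1 (Pavir.7KG102300) and 0 were among these. Without Liberty 1 and 0 genes passed (edgeR; 1495 and 3783 at an unadjusted p under 0.05; DESeq2 called 169 and 197 with all genotypes).

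The drought libraries of 1-78 in block 11 and of Trailblazer in block 5 lay apart from the other 38 on the first principal component. Reads on unplaced gene IDs do not account for it, since over placed IDs alone the gap to the others was 1.15 SD, against 1.16 SD over all IDs. A swap of labels between these 2 genotypes is argued against as well: the Trailblazer library had counts for 6 of 88 genes that mark other genotypes, against at least 48 in libraries of those genotypes, and the 1-78 library lacked 15 of 81, within the 5 to 17 of other 1-78 libraries; the bound of under 5 set for that test ignored that such genes are missed in any single library. The 1-78 library was nearer to the mean of Trailblazer than to that of 1-78 (correlations of 0.146 and -0.125, or 0.026 and -0.005 with both outlying libraries kept out of the means), and it had counts for markers of each other genotype, 75 of 390 of Trailblazer, 47 of 149 of 2-37, 16 of 37 of Liberty and 23 of 86 of 2-43, against at most 31, 19, 7 and, outside the recovery library of block 1, 16 in other 1-78 libraries; the rise is not that of 1 genotype alone, and material of others in it stays open. A stronger drought response may be a cause, with responses of 3.62 and 3.45 against at most 3.36 in the other 15, but it cannot be told apart from other sources, because their lower genes fell further (medians of -2.31 and -2.33 against -2 or higher) and their higher genes (1.31 and 1.12) stayed inside the range of the others (up to 1.41).

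Fewer genes differed between drought and watering with the block as a term, 1053 in place of 3344. A difference between block 1 and the other blocks among drought plants stays open. There 8 genes passed (5 against 12 libraries; edgeR, 5347 at an unadjusted p under 0.05), below the bound set for that test, but a bound on single genes was too strict for a shift spread over many: the drought response was smaller in block 1, at 1.64 ± 0.69 (SD, n = 5) against 2.4 ± 0.88 (n = 12; exact permutation test within genotypes, two-sided, p = 0.0267). All watered libraries of week 7 were in block 1. That fewer drought libraries carry the comparison may explain it, but this cannot be told from these libraries. In 12 of 32 possible sets of 5 drought libraries outside block 1, the number of genes ran from 84 to 1464, with a median of 340. Not every set therefore lay below the bound set for that test. The 5 drought libraries of block 1, against the same 5 watered libraries, gave 1 gene (edgeR, 5276 at an unadjusted p under 0.05). That is fewer than in any of these 12 sets, at the same number of libraries.

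The recovery libraries of 1-78 and of 2-43 in block 1 were closer to each other than any other 2 libraries. A repeated deposit of 1 library is argued against by the chi-square of 8.85 per gene. A wrong label on 1 of them stays open: the 1-78 library had 16 of 23 markers of 1-78 and the 2-43 library 37 of 63 of 2-43, but each held the other's markers in about the number found there (36 of 63 and 16 of 23), another 2-43 library had 17 of 40 markers of 1-78, which the bound set for that test ignored, and the 2-43 library correlated better with the mean of 1-78 (0.186) than with that of 2-43 (0.037), the 1-78 library about equally with both (0.077 and 0.085). Material of both individuals in both libraries is a candidate explanation: the 1-78 library had 36 of 63 markers of 2-43, at 84.4 CPM against 113 ± 25 CPM in libraries of 2-43, and other 1-78 libraries had at most 23, but it stays open, because the 2-43 library had 16 of 23 markers of 1-78 while another 2-43 library had 17 of 40, so the bound set on the number of markers was not passed. The marker sets differ in size, and as percents, which were looked at only afterwards and among 3 ways of choosing markers, the values were 57.1% against at most 26.7% and 69.6% against at most 42.5%; no biological explanation was tested.

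Other splits of the same libraries bear on whether chance can be excluded. For drought against watering, 2 of 32 splits gave as many genes, with a real value of 3344 and 6532 in the highest other split, so chance was not excluded; that split had both outlying drought libraries among the controls, which points to a structure of the samples. Without these 2 libraries, left out after the results were seen, only the real split of 32 gave as many (2912, highest other 198). For the change of the difference between drought and recovery 2 of 32 splits gave as many (490, highest other 6760), again with both libraries among the controls, and without them 1 of 32 (429, highest other 135). Only the real split, 1 of 32, gave as many for recovery against watering (274, highest other 6) and recovery against drought (8763, 78). The same held for the individuals against Liberty (76, 25), Trailblazer against Liberty (3134, 567) and the F-test among individuals (1013, 2). That share is the smallest that 32 splits can give and was not adjusted over the comparisons, so it argues against chance without excluding it. These splits did not keep libraries of a block together and so leave block differences open: with the block as a term the 5 counts were 306, 7606, 4, 2941 and 926, and recovery against watering gave 0 in block 5 alone (edgeR; 4871 at an unadjusted p under 0.05) and 1021 with DESeq2 over all blocks. For the watered groups, 16 of 16 splits gave as many as the real value of 0 (highest other 0), and 16 splits are too few for a share under 0.05.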

How the results depend on the processing

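Leaving out 2 outlying drought libraries, the pair of recovery libraries with markers of both individuals, or the most abundant gene, the bounds without the highest library, the interactions without 1 genotype, and the fits of block 1 or block 5 alone, were tests chosen only after the results were seen. No value changed direction past its threshold under any alternative. Of 1478 values of named genes under alternatives, 91 lost the threshold and 1 gained it. These values leave out the interaction genes, each of which lost its call in at least 1 fit. They include Pavir.4NG154200 in comparisons where it had not passed and so could not lose the threshold. With DESeq2 size factors or without the most abundant gene each count of the 10 comparisons stayed within 1.5 times. With no filter the change of the difference between drought and recovery gave 285 genes, the individuals against Liberty 122 and the drought interaction 10; with the stricter filter the individuals against Liberty gave 21 and the F-test among individuals 422. With the replicate block as a term drought gave 1053, the change of the difference 13 and the individuals against Liberty 4. The interactions gave 0 (edgeR, 1829 at an unadjusted p under 0.05, against 169 in DESeq2 without a block term) and 1. The block moved no other of these counts by over 1.5 times, but the genes called changed more. The block fit kept 66.1% of the 274 genes of recovery against watering and 71.7% of the 1013 among the individuals. It kept 83.3% of those of recovery against drought and 88.7% of those of Trailblazer against Liberty. Blocks 1 and 5 alone gave 979 genes for drought, 178 for recovery against watering, 2279 for recovery against drought, 5 for the change of the difference, 7 for the individuals against Liberty and 124 among the individuals, with fewer libraries. The 2 treatments alone gave 1929 for drought and 454 for recovery against watering, and kept 52.7% and 76.6% of the genes of the main fit. Recovery against watering gave 139 without 2-37, 482 without 2 outlying drought libraries, 182 without the pair and 0 in block 5 alone (edgeR; 4871 at an unadjusted p under 0.05), and drought in block 1 alone gave 1. Without 1-78, 2-43, Liberty or Trailblazer the drought interaction gave 0, 0, 1 and 0 genes (edgeR; 2134, 1446, 1495 and 2041 at an unadjusted p under 0.05), and without 1-78, Liberty or Trailblazer that of rewatering gave 7, 0 (3783 at an unadjusted p under 0.05) and 6. DESeq2 gave 5327 for drought, 1021 for recovery against watering (55.5% higher, against 32.8% with edgeR), 40 for the watered groups, 1688 for the change of the difference, 239 for the individuals against Liberty (56.9% higher, against 25%), 2001 among the individuals, and 169 and 197 for the interactions. Without single libraries the counts ran from 1356 to 4075 for drought, 25 to 384 for recovery against watering, 7201 to 9617 for recovery against drought, 0 to 3 for the watered groups, 113 to 774 for the change of the difference, 42 to 111 for the individuals against Liberty, 2499 to 3331 for Trailblazer against Liberty, 665 to 1201 among the individuals, and 1 to 5 and 0 to 15 for the interactions; a single remaining library was taken to vary like the other groups. Apart from the smaller number of libraries or genes in some settings, and the tests given above of the lower drought count with the block, the cause was not tested. The gene list tests were not run, since no gene ID could be matched to a name. With 5 watered libraries, 2-fold changes were mostly below what the simulated data recovered (8.96% for drought).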

Other observations

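The tests of genes without counts in Trailblazer, and other count minimums for them, were chosen only after the results were seen.

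Over the genes called under drought without a genotype's own libraries, recovery libraries were set against the watered library of week 8 of their genotype and drought libraries against that of week 7. In Liberty the lower genes were at a median log2 difference of -1.29 ± 0.15 (SD, n = 2) after 1 week of renewed watering, against -1.59 ± 0.57 (n = 2) under drought. In 2-43 they were at -0.59 ± 0.17 (n = 4) against -0.91 ± 0.49 (n = 5), in 1-78 at -0.16 ± 0.37 (n = 4) against -1.49 ± 0.58 (n = 5), in Trailblazer at 0.08 ± 0.6 (n = 2) against -2.03 ± 0.42 (n = 2), and in 2-37 at -0.53 (n = 1) against -1.51 ± 0.38 (n = 3). The higher genes were at 0.28 ± 0.29 in recovery against 0.82 ± 0.47 under drought in Liberty, 0.18 ± 0.16 against 0.62 ± 0.26 in 2-43, -0.14 ± 0.13 against 0.69 ± 0.42 in 1-78, -0.4 ± 0.57 against 0.83 ± 0.41 in Trailblazer and -0.11 against 1.15 ± 0.24 in 2-37. The difference between genotypes in these medians was not tested. Each watered reference was 1 library, so the SDs leave out its error. The Trailblazer library watered for 8 weeks stood apart in several measures. Both Liberty recovery libraries correlated better with the mean of 2-37 (0.016 and 0.022) than with that of Liberty (-0.075 and 0.009), all weak values. They had counts for 37% and 42% of the markers of 2-37, within the 35.6% to 49.6% of the other Liberty libraries.

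Trailblazer had 0 counts over its 6 libraries for 82 genes with at least 100 counts in each other genotype, while 5 such genes were found for 2-37, 1 for 1-78 and 0 for 2-43 and Liberty. Of genes seen in 1 genotype alone, 29 were found in Trailblazer. Genes of the reference may be missing or diverged in Trailblazer, but the ratio of 2.83 does not decide it: a gene absent from Trailblazer has 0 counts over 6 libraries, and a gene seen only there has 0 over the libraries of 4 genotypes. With up to 3 counts allowed in the others, 45 genes were seen in Trailblazer. With a minimum of 50 or 200 counts 166 and 34 genes were absent.

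Genes called between genotypes may lie in blocks of shared haplotype. Genes were put in order of their ID numbers within a chromosome, since no gene positions were used. The next gene ID was also called 2.04 times as often as in 1000 random orders for Trailblazer against Liberty and 2.76 times as often among the individuals. The ratio was 1.53 for drought and 1.17 for recovery against drought (permutation of the gene order, p = 0.000999 each, the smallest that 1000 orders can give). Neighbouring copies that share reads were not excluded.

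The hypothesis that plants of a cultivar differ from each other more than libraries of a numbered individual could be examined per library only. Genes with 0 counts in a library and at least 50 in another of the same genotype, at an equal total of 4006128 counts, numbered 232 ± 94.8 (SD, n = 12) per library in the cultivars and 115 ± 48.4 (n = 28) in the individuals (permutation test, p = 1e-05, the smallest that the draws can give). Without 2 outlying drought libraries they were 172 and 96.3 (permutation test, p = 0.00011), and the excess was that of Liberty, with a mean of 235 over its 15 pairs of libraries against 97 over 10 pairs in Trailblazer and 79.2 to 111 within the individuals. At this equal total the most abundant gene still took 0.0753% to 13.8% of the counts of a library, which moves the depth left for other genes. The permutations moved single libraries, whose values share pairs within a genotype. Their p-values therefore treat libraries as replicates and do not measure a difference between cultivars and individuals. With 2 cultivars of different ploidy, cultivar and genotype cannot be told apart.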
